A study of Trichoderma reesei with 12 samples.

How the data were processed

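RNA was taken from mycelium of the filamentous fungus Trichoderma reesei grown on cellulose for 96 h. The parent strain lacks ku80, a gene of non-homologous end joining whose loss makes targeted gene replacement more efficient. The second strain also lacks tmk3, which encodes a mitogen-activated protein kinase. Each strain was kept in constant darkness or in constant light, with 3 libraries in each of the 4 groups. The labels name no complemented strain and no other deletion strain. An effect of losing tmk3 therefore cannot be told apart from any other difference between these strains. The terms deletion effect and without tmk3 stand below for the difference between the strains. Libraries were made with a stranded kit after removal of ribosomal RNA, per the labels' protocols.

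The deposited table holds whole-number read counts per gene model, with no normalization by the authors. HISAT2 2.2.1 is named per the submitters' processing notes, and the QM6a transcripts of the complete genome sequence are named in the series' design text. The counting tool's version, its strand setting and any filter are not given in the sources used here. Counts of overlapping genes and of near-identical gene copies are therefore uncertain. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

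Each column was assigned to its sample through the label that carries the column's name, and 0 columns were left unused. The table lists 10879 identifiers. Of these, 10876 consist of a series letter (7 letters in all), a running number and a W or C, and 3 are mating-type gene names. None of them (0 of 10879) matched the 9116 entries of the reference gene table used here, and the file does not pair identifiers with gene names. The 24 gene lists fixed before the data were examined could not be applied: their 82 gene numbers were all present in the reference table and 0 were in the count table, and the reference table has no product names. The tests of gene lists and the check of the tmk3 transcript were not run for that reason.

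Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 8998, libraries were scaled by TMM, and 1 model with 4 group means was fitted to all 12 libraries. Contrasts were tested with edgeR's quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The contrasts were the deletion effect in darkness and in light, the light effect in each strain, and the interaction. Fold changes are log2. The value given as SE is the absolute log2 fold change divided by the square root of the F statistic. It approximates a standard error and is unreliable where a group holds 0 or few counts. Levels are edgeR CPM values from the TMM-scaled library sizes, as mean ± SD. Principal components used log2 CPM with a prior count of 2.

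Because identifiers could not be named, the rule fixed beforehand allowed at most 2 that rose and 2 that fell per contrast. These had the largest change among called genes with a mean log2 CPM of at least 3 and no overlap between the 6 libraries compared. The condition on overlap was not applied to the interaction. All other identifiers and regions were chosen after their values were seen. Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio of group totals carries a 95% exact Poisson interval. Both use TMM-scaled library sizes. Intervals and floors cover counting error only.

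Consecutive numbers within a letter series were read as neighbouring genes, an assumption from the form of the identifiers, since the file has no coordinates. Analyses of neighbours, series ends, windows, lost genes and orientation were added after seeing the data. Called genes with at least a 2-fold change were counted in windows of 10 tested genes. The windows moved along gene by gene, so they overlap, a cluster enters several of them, and their number is not a number of regions. Their maximum, and the number of windows with at least 6, were set against 100000 permutations of the genes in Python 3.11.15 with NumPy 2.4.6. Series ends were the first and last 50 numbers of each series, tested with Fisher's exact test (two-sided, adjusted over the 10 tests). Genes near 0 in the deletion strain were those with at least 20 counts in every parent library and less than 5% of the parent CPM in both light conditions.

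The procedure was tested on simulated data for the deletion in darkness, with 8998 genes of which 200 were changed. It recovered 45% of 2-fold and 90% of 4-fold changes, with 6 false calls (4.26% of calls). Each gene was given the same spread in all groups. In the data the coefficient of variation was 0.335 for the dark pair of groups and 0.144 for the light pair. The simulation also changed far fewer genes than were called in the data. It therefore cannot show false calls that come from unequal spread, and its recovery need not hold for these data. Alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a fit to only the 2 groups compared, the replicate number as a block, a stricter threshold, and leaving out each library in turn. Leaving out a pair of dark libraries together was added after seeing the data.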

Results

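The series compared transcript levels of Trichoderma reesei with and without the kinase gene tmk3, in constant darkness and in constant light, in mycelium grown on cellulose for 96 h. The 12 libraries held between 11599300 and 17702344 counts. A count of 0 allowed a level of up to 0.169 CPM in the deepest library and 0.259 CPM in the shallowest. The first principal component carried 51.3% of the variance and separated light from darkness, and the second carried 26.8% and separated the strains. The common biological coefficient of variation was 0.26. The parent in darkness was the most variable group, and its replicate 2 had the lowest TMM factor (0.761). No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom between 12.9 and 482). The tmk3 transcript could not be read by name, so the deletion itself was not checked in the counts.

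**Figure D1:**
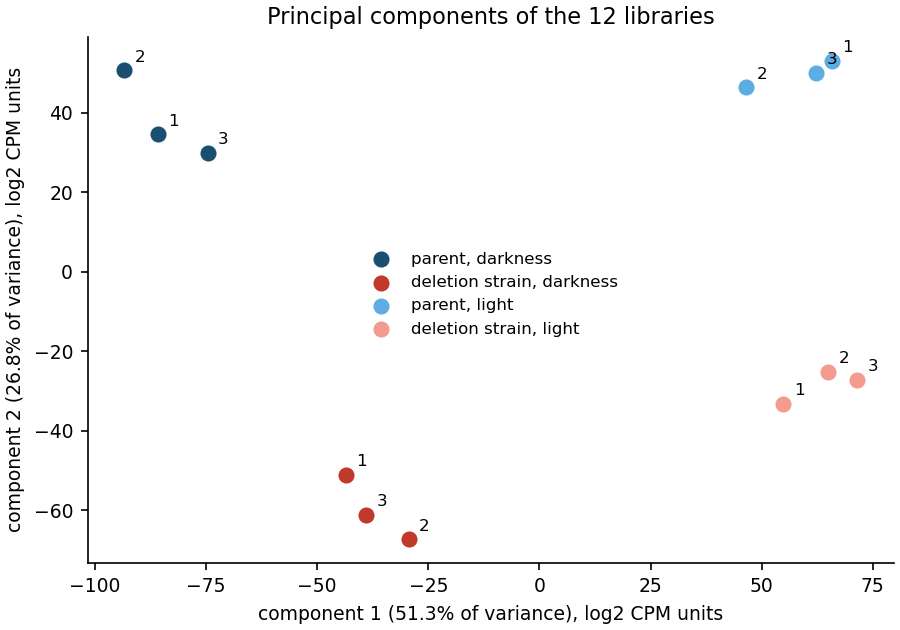
Each point is 1 of the 12 libraries on the first and second principal components of log2 CPM, coloured by strain and light condition. The first component (51.3% of the variance) separates light from darkness and the second (26.8%) separates the strains.

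The first comparison asked which transcripts differed between the deletion strain and the parent in darkness. TrE0049C rose from 0.123 ± 0.0354 to 53.2 ± 8.74 CPM (SD, n = 3), a log2 fold change of 8.64 (SE 0.50, edgeR adjusted p = 1.63e-06). TrB0209C rose from 4.44 ± 1.73 to 701 ± 326 CPM, by 7.31 (SE 0.41). TrB0628C fell from 254 ± 323 to 1.36 ± 1.54 CPM, with a log2 fold change of -7.49 (SE 1.91, edgeR adjusted p = 0.0103), and TrE0170C fell from 247 ± 264 to 1.5 ± 1.13 CPM, with -7.33 (SE 1.28). The size of both falls depended on single libraries: they were -5.63 and -6.06 without replicate 2 of the parent, and -9.04 and -8.18 without replicate 3 of the deletion strain. TrC1166C, the most abundant transcript of the dark parent at 1.45% ± 0.219 of counts and singled out after its values were seen, fell with a log2 fold change of -5.24 (SE 1.11, edgeR adjusted p = 0.00382), or -6.49 without replicate 1 of the deletion strain, which held 13168 counts of it against 2126 and 4022 in the others.

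In all, 1723 genes rose and 1941 fell in darkness without tmk3, 3664 of 8998 tested. Changes of at least 2-fold were seen in 1006 of those that rose and 1039 of those that fell. Among the 100 most abundant genes, 17 rose, 35 fell and 48 were not called. Falls and rises were both grouped along the identifiers, with 139 and 17 windows of 10 tested genes holding at least 6 (p = 1e-05, the smallest the permutations can give, and permutation p = 0.00066). The highest number of rises in a window was 7 (permutation p = 0.092). In the first of 4 windows tied for the most falls, 10 of 10 tested genes between TrE0657C and TrE0669C fell by at least 2-fold (permutation p = 1e-05), with a median log2 fold change of -4.64, and 9 did so without replicate 2 of the parent. Within 50 numbers of a series end, 28.0% of genes fell by at least 2-fold, against 10.6% elsewhere (odds ratio 3.28, 95% interval 2.63 to 4.06, Fisher's exact test, adjusted p = 9.79e-24). This test, here and in the other comparisons, counts genes as independent, while neighbouring genes changed together (r = 0.25), so its interval is too narrow and its p too small. With libraries scaled by total count alone, 2484 rose and 1038 fell, and the median over all genes was higher by 0.28 on the log2 scale. Fitted to these 6 libraries alone, the count was 2183.

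Replicate 1 of the deletion strain in darkness held 9.01% (95% interval 8.0 to 10.1) of the parent level of 9 identifiers that were near 0 in the other deletion libraries, where the share was at most 0.83%. Most of this was 1 identifier: 189 of the 289 counts were of TrC0725W. Single identifiers differed, with 5 counts of TrD1420C and 32 of TrD1425W, against 360 and 575 in the dark parent group. The interval covers counting error of the pooled counts only. These 9 were chosen after their values were seen, and with 3 further identifiers of the end of series D, which held counts in another deletion library, the share was 6.63%, against at most 1.72% in the other deletion libraries. In the dark parent, 105 genes with more than 20 CPM in their highest replicate differed by more than 15-fold between replicates, and these 105 were all highest in replicate 2. Of the 104 tested, 48 fell in this comparison and 64 fell in light in the parent.

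The second comparison asked the same in constant light. TrD0285W rose from 0.712 ± 0.194 to 42.5 ± 1.44 CPM, a log2 fold change of 5.90 (SE 0.34, edgeR adjusted p = 2.94e-06), and TrB0082C rose from 3.83 ± 0.621 to 222 ± 9.89 CPM, by 5.85 (SE 0.25). Both also rose in darkness, by 6.99 and 5.56. TrC0725W fell from 278 ± 18.2 to 0.669 ± 0.589 CPM, with a log2 fold change of -8.67 (SE 1.12, edgeR adjusted p = 0.000357). TrB1746C fell from 33.9 ± 11 to 0.0777 ± 0.0792 CPM, with 3 counts left in the group, a ratio of 434 (95% interval 148 to 2107). Its call was lost when any 1 of the 3 deletion libraries in light was left out, at log2 fold changes of -9.48, -8.58 and -8.11 against -8.60 and with larger SEs (edgeR adjusted p between 0.0537 and 0.0606). These fits take the spread from the dark libraries as well. Fitted to the light libraries alone, TrB1746C was called at -8.60 (SE 0.48, edgeR adjusted p = 8.01e-06).

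In light, 969 genes rose and 880 fell without tmk3, 1849 of 8998. Of these, 645 rose and 566 fell by at least 2-fold. All 10 tested genes from TrD1415W to TrD1430C fell by at least 2-fold (p = 1e-05, the smallest the permutations can give), with a median of -6.84. Several of them, such as TrD1420C and TrD1425W, held 0 counts in the deletion strain in light. Their fitted fold changes depend on the prior count, so the median is not a measured size. At series ends 19.0% of genes fell by at least 2-fold, against 5.58% elsewhere (odds ratio 3.98, Fisher's exact test, adjusted p = 2.33e-22). The count was smaller than in darkness, but this order turned when each pair of groups was fitted alone: 3024 genes were called in light and 2183 in darkness, at coefficients of variation of 0.144 and 0.335.

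**Figure D2:**
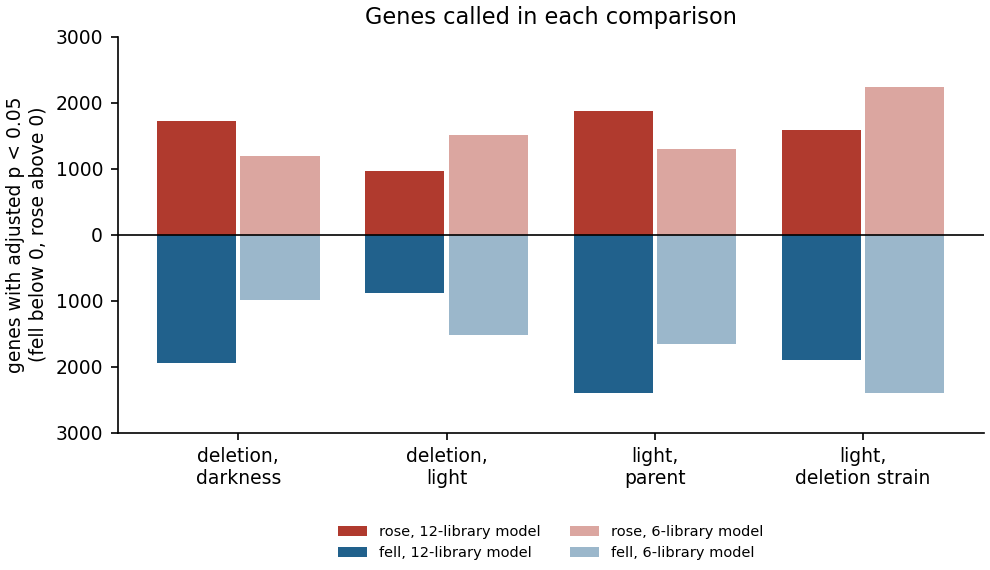
Number of genes that rose (above 0) and fell (below 0) at an adjusted p below 0.05 in 4 comparisons, with the model of all 12 libraries in dark bars and the model of the 6 libraries compared in pale bars. The deletion has more calls in darkness than in light in the first model (3664 and 1849) and fewer in the second (2183 and 3024).

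A stretch of 24 consecutive identifiers at the end of series D, from TrD1420C to TrD1443C, was near 0 in the deletion strain. Some of the 24 were near 0 in the parent too, such as TrD1426W and TrD1443C with 0 counts in every group. Together the 24 held 29769 counts in the dark parent and 794 in the dark deletion strain, and 6680 and 47 in light. Most of the dark parent counts were of TrD1439W (7782) and TrD1440W (17150). Just before the stretch, TrD1417C fell from 1794 to 32 counts in light, so the edge of the stretch is not sharp. Of the 794, 527 were in replicate 1 of the dark deletion strain, and without it 267 remained, or 8.71 CPM by total counts in place of 18.2. TrD1424C went from 44.7 ± 9.46 to 0.129 ± 0.120 CPM in light, a log2 fold change of -8.33 (SE 0.98, edgeR adjusted p = 0.000187). TrD1440W kept 162 counts in replicate 3 of the dark deletion strain. Over all series, 9 of 7364 identifiers with enough parent counts were below 5% of the parent in both light conditions, of which 6 lie in this stretch and 3 elsewhere (TrA1280W, TrC0725W and TrF0148W). The stretch and these identifiers were picked after their values were seen.

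**Figure D3:**
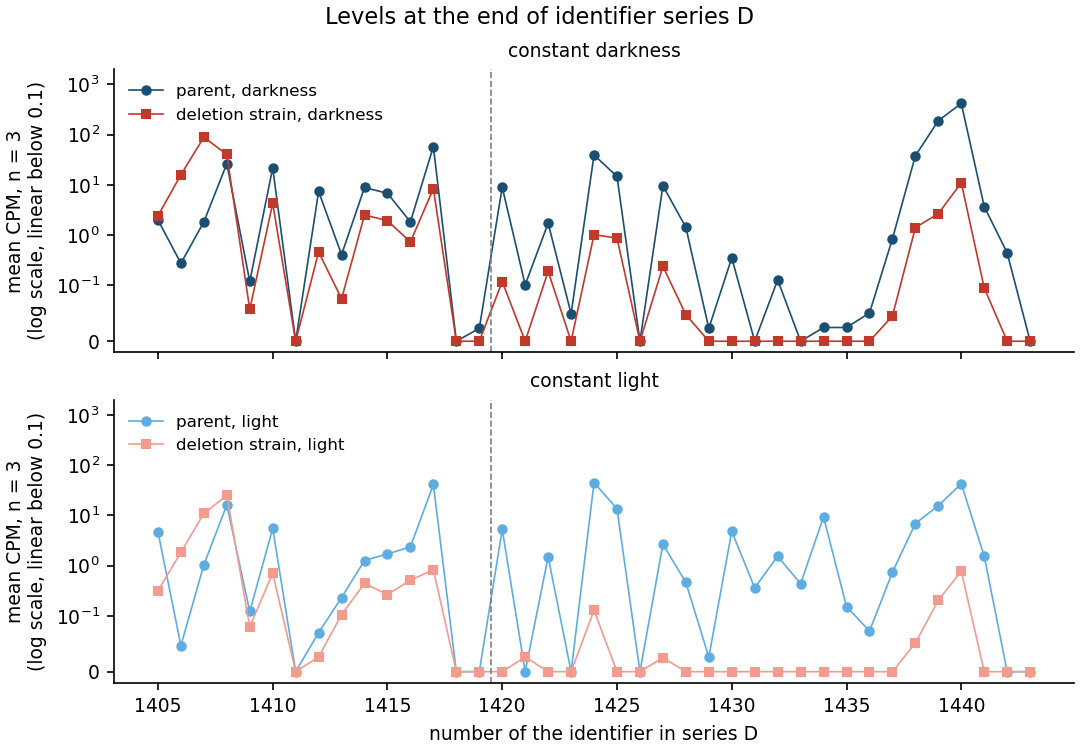
Mean CPM (n = 3, log scale that turns linear near 0, no error bars) of the identifiers at the end of series D in order of their number, in darkness (top) and light (bottom). To the right of the dashed line, from TrD1420C on, the deletion strain holds 47 counts in light against 6680 in the parent.

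The deletion effects in darkness and in light shared genes. In both conditions 602 genes rose, against 186 for independent lists, and 444 fell, against 190. Another 141 were called in opposite directions, against 378. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.52 and Spearman's rho 0.45. TrB0082C and TrD0285W were among the genes that rose in both.

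**Figure D4:**
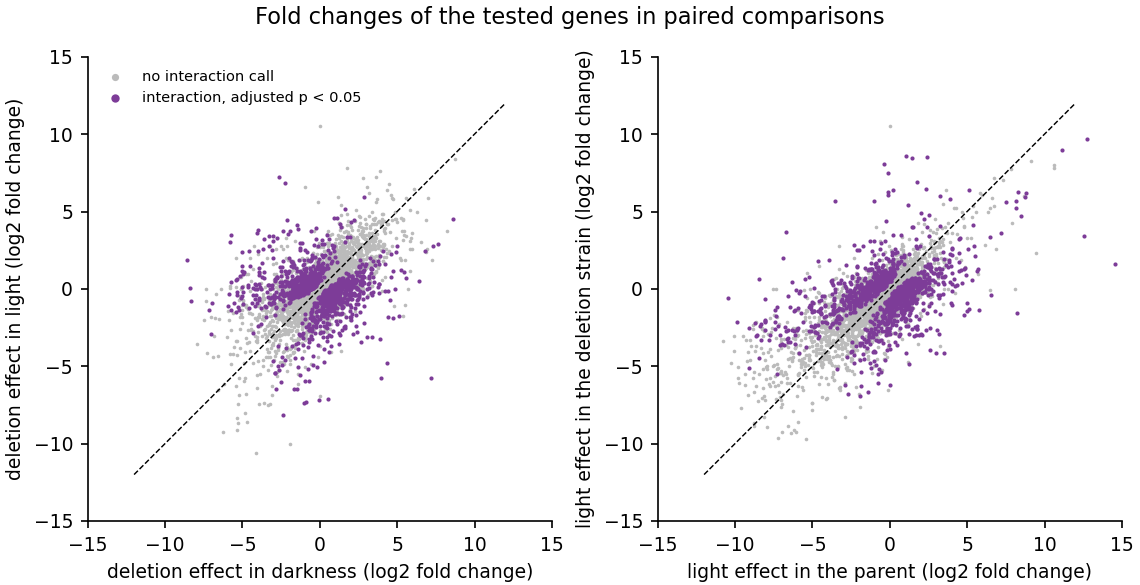
Each point is a tested gene, with the log2 fold change of the deletion in darkness against that in light (left) and of light in the parent against that in the deletion strain (right). Genes with an interaction call are purple, the dashed line marks equal changes, and r is 0.52 on the left and 0.70 on the right.

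The third comparison asked how the parent differed between light and darkness. TrE0391W rose from 9.77 ± 5.52 to 66294 ± 6521 CPM, a log2 fold change of 12.73 (SE 0.94, edgeR adjusted p = 2.22e-06), and took 6.51% ± 0.546 of all counts in light. TrC1533C had 0 counts in the dark parent and 215 ± 120 CPM in light, at least 3010.2-fold higher by group totals. TrB1967C fell from 50.4 ± 14.4 CPM to 2 counts in the group, a ratio of 1132 (95% interval 313 to 9354), and its log2 fold change of -9.86 was -9.25 without replicate 1 of the parent in light. TrE0664C fell from 479 ± 523 to 0.529 ± 0.394 CPM, with a log2 fold change of -9.73 (SE 1.67), or -8.30 without replicate 2 of the dark parent.

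In the parent, 1868 genes rose and 2404 fell in light, 4272 of 8998. At 2-fold or more, 803 rose and 1584 fell. Among the 100 most abundant genes 17 rose and 41 fell. Windows of 10 tested genes with at least 6 rises numbered 16, and with at least 6 falls 283 (both p = 1e-05, the smallest the permutations can give). For rises the highest number in a window was 6 (permutation p = 0.281). The same part of series E fell here, with 10 of 10 tested genes between TrE0659C and TrE0670C down by at least 2-fold (permutation p = 0.00019, median log2 fold change -8.35), of which TrE0664C is 1, and 9 did so without replicate 2 of the dark parent. This comparison and the deletion in darkness share the dark parent libraries, so the falls are not separate findings. Of these 10 genes, 0 were called for the deletion in light, and 5 fell in light in the deletion strain (median -3.83). At series ends 37.2% of genes fell by at least 2-fold, against 16.5% elsewhere (odds ratio 3.0, Fisher's exact test, adjusted p = 3.84e-25). Rises were also more frequent there, 12.6% against 8.72% (odds ratio 1.5, Fisher's exact test, adjusted p = 0.00903). For rises the same test did not pass for the deletion in darkness (odds ratio 1.22, adjusted p = 0.174) or in light (0.83, adjusted p = 0.411). Nor did it for light in the deletion strain (1.37, adjusted p = 0.111). Scaled by total count alone, 2192 rose and 1882 fell, with the median higher by 0.15 on the log2 scale.

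The fourth comparison asked the same in the deletion strain. TrE0391W rose from 57.4 ± 39.3 to 46803 ± 7715 CPM, a log2 fold change of 9.67 (SE 0.84, edgeR adjusted p = 1.16e-05), and took 4.97% ± 0.751 of counts. TrD1022C rose from 0.423 ± 0.146 to 217 ± 38.7 CPM, by 8.97 (SE 0.31), and in the parent by 11.14. TrF0715W fell from 29.4 ± 3.51 CPM to 2 counts in the group, a ratio of 565 (95% interval 156 to 4672), with a log2 fold change of -8.91. Both counts lay in replicate 1 of the deletion strain in light. Without that replicate 0 counts were left in the group, so the fitted value of -11.72 depends on the prior count. TrC1547W fell from 4.19 ± 0.913 CPM to 0 counts, at least 52.7-fold lower by group totals.

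In the deletion strain, 1590 genes rose and 1895 fell in light, 3485 of 8998, and 530 and 1237 did so by at least 2-fold. The count was below that of the parent, but in fits to each pair of groups alone it was above it, 4629 against 2957. Between TrG0124W and TrG0135W, 10 of 10 tested genes fell by at least 2-fold in the deletion strain (permutation p = 3e-05, median -4.42) and 10 fell in the parent (median -2.42). At series ends 36.0% of genes fell by at least 2-fold, against 12.5% elsewhere (odds ratio 3.93, Fisher's exact test, adjusted p = 9.72e-36). Under the stricter threshold the split was 424 up and 1006 down.

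**Figure D5:**
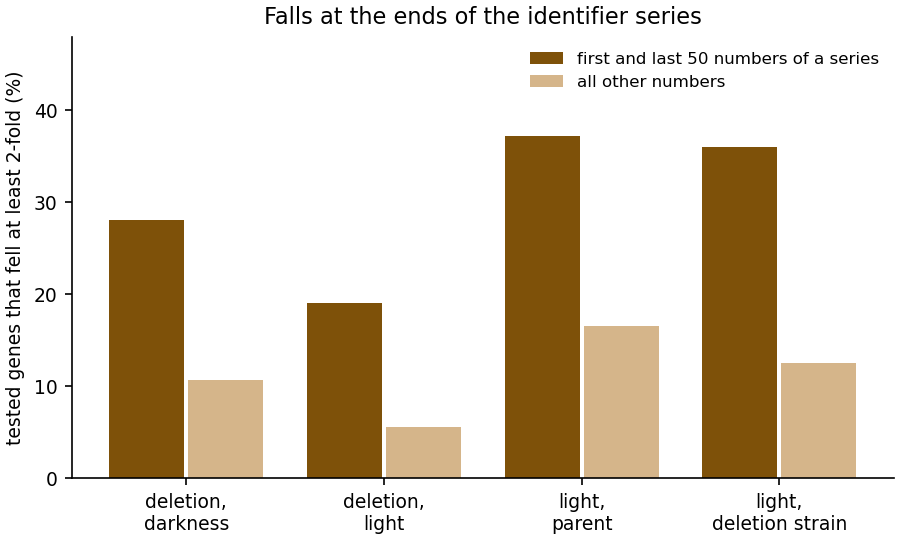
Percentage of tested genes that fell by at least 2-fold among the first and last 50 numbers of a series and among all other numbers, in 4 comparisons. Falls were more frequent at the ends, with 36.0% against 12.5% for light in the deletion strain.

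The light responses of the strains shared genes as well. In both strains 932 genes rose, against 330 for independent lists, and 1270 fell, against 506. Only 125 were called in opposite directions, against 818, and r was 0.70 (rho 0.62) across genes. TrE0391W and TrD1022C rose in both strains, with interactions of -3.06 (edgeR adjusted p = 0.035) and -2.17 (edgeR adjusted p = 0.016). For TrE0391W the strains differed in darkness, where the deletion strain was higher by 2.56 on the log2 scale (edgeR adjusted p = 0.00805), while in light the difference was -0.50 (edgeR adjusted p = 0.609). The dark deletion libraries held 982, 208 and 1557 counts of it, and the dark parent libraries 52, 139 and 193. Replicate 2 of the dark deletion strain was thus close to the parent, and the dark difference rests on replicates 1 and 3. The interaction of TrE0391W draws on the same libraries.

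The interaction tested whether the deletion effect differed between light and darkness. It was called for 1269 genes, 575 higher and 694 lower. TrE0016W fell in darkness, from 18.9 ± 8.40 to 0.354 ± 0.251 CPM, and rose in light, from 1.62 ± 0.541 to 18 ± 10.2 CPM. TrF1202W had 0 counts in the dark parent and 8 in the dark deletion strain, and in light fell from 53.8 ± 5.91 to 1.90 ± 0.171 CPM. Of the 1269 genes, 788 (62.1%) had a smaller light response in the deletion strain, 473 responded to light in the parent alone, 306 in the deletion strain alone, and 125 in opposite directions. The count was 1958 without replicate 2 of the dark parent and 842 without replicate 2 of the deletion strain in light, and scaled by total count alone 345 were higher and 715 lower, with a median lower by 0.17. Interaction calls of at least 2-fold were more frequent at series ends in both directions (8.16% against 4.53% higher, 11.3% against 5.35% lower).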

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

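The tests of explanations and the counts over other splits of the samples were written after the results were seen.

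The deletion effect differed between light and darkness, by the interaction test, for 1269 genes. Among them TrE0016W had an interaction of 9.22 (SE 0.88, edgeR adjusted p = 0.000145) on the log2 scale, with a fall in darkness and a rise in light, and 9.91 without replicate 1 of the dark deletion strain. TrB1967C had 7.75 (SE 1.46, edgeR adjusted p = 0.00559), and without replicate 1 of the deletion strain in light its value was 5.18 (edgeR adjusted p = 0.078), the call being kept at 7.13 without replicate 1 of the parent in light. TrC1533C had -12.97 (SE 2.34, edgeR adjusted p = 0.00714), a fitted value that depends on the prior count since the dark parent held 0 counts, and with replicate 2 of the dark parent and replicate 1 of the dark deletion strain both left out it was -10 (adjusted p = 0.0862). Without the latter alone it was -9.94, with the call kept (adjusted p = 0.0408). TrF1202W had -9.16 (SE 0.68, edgeR adjusted p = 0.000126), also against 0 counts in the dark parent, so this SE is unreliable. DESeq2 gave -8.45 with an SE of 1.32.

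For the interaction, 2 of 100 splits drawn from 200 gave as many genes, the real one included. Splits that mix the strains carry the deletion effect into the spread and called a median of 0 genes, so this share says little about the interaction apart from the deletion effect. The highest other split, with 3604 genes, swaps the strain labels in 1 light condition and so holds the shared deletion effect, and the next gave 940. For the other contrasts 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes: 2183, 3024, 2957 and 4629 for the deletion in darkness, the deletion in light, light in the parent and light in the deletion strain, with 0 as the highest other.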

How the results depend on the processing

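Leaving out a pair of dark libraries, and leaving the end of series D out of the neighbour and series-end analyses, were chosen after seeing the data, as were those analyses themselves, the share of smaller light responses, TrC1166C and the counts at the end of series D without replicate 1 of the dark deletion strain, and TMM-scaled ratios and bounds. The other alternatives were fixed before the data were examined. No gene named by the rule fixed beforehand changed sign in the alternatives run for it. TrC0725W had no adjusted p from DESeq2, and identifiers picked after their values were seen, such as TrD1424C, TrA1280W and TrF0148W, were not rerun. The balance of rises and falls turned in several settings. For the deletion in darkness 1723 against 1941 became 2484 against 1038 by library size alone, 788 against 714 at the stricter threshold, 1186 against 997 in the fit to 2 groups, 1601 against 1558 with the block, 1828 against 1814 with both dark libraries left out, and 1569 against 1558 and 1500 against 1497 without replicate 1 or 3 of the deletion strain. Without its replicate 2 rises also outnumbered the falls, of which there were 1321. For the deletion in light 969 against 880 became 1508 against 1516 in the fit to 2 groups, 916 against 925 with no filter and 694 against 699 without replicate 3 of the parent. For light in the parent 1868 against 2404 became 2192 against 1882 by library size alone. Without the end of series D the odds ratio of falls at series ends in the deletion in light was 3.37. At an adjusted p below 0.01 and at least 2-fold, the counts were 1502, 880, 1969, 1430 and 504 for the deletion in darkness, the deletion in light, light in the parent, light in the deletion strain and the interaction, a stricter threshold by construction. Fitted to the 2 groups compared, the deletion counts were 2183 in darkness and 3024 in light, with coefficients of variation of 0.335 and 0.144, and the light counts were 2957 in the parent and 4629 in the deletion strain, so both orders turned. Leaving out 1 library at a time gave 2741 to 4002, 1288 to 1862, 3467 to 4603, 2552 to 3005 and 842 to 1958 genes in the same order, and 766 to 1399 and 1690 to 2751 for the overlaps of deletion and of light effects. The cause of the interaction's range was not tested. DESeq2 called 4090, 2293, 4631, 3835 and 1806. Leaving out both dark libraries kept 2968 of the 3664 calls in darkness. With the replicate number as a block the counts were 3159, 1587, 3864, 3160 and 958, and the overlaps 892 and 1975. Libraries with the same number did not deviate together (r between -0.37 and 0.12). These values gave no sign that the numbers pair the samples, but with 3 libraries per group they cannot exclude it. TrB0628C had a log2 fold change of -5.98 under the block (edgeR adjusted p = 0.0673, range of adjusted p over its alternatives 6.14e-05 to 0.0673). Tests of the gene lists and of the tmk3 transcript were not run, since no identifier matched. The simulation recovered 45% of 2-fold changes for the deletion in darkness, with equal spread in all groups and few changed genes, so this share need not hold for the data.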

Other observations

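All tests in this part were chosen after the results were seen.

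Neighbouring identifiers changed together. Over 7731 pairs of consecutive numbers, r of the fold changes was 0.25 for the deletion in darkness, 0.27 in light, and 0.33 for light in the deletion strain (each p = 1e-05, the smallest the permutations can give). Pairs read as transcribed away from each other (C then W) may share more of their change than pairs read towards each other. Their r was higher in all 5 contrasts, by 0.220 or more, for example 0.54 against 0.17 for light in the deletion strain. This rests on reading W and C as strands, which the file does not state.

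The deletion in darkness and light in the parent, which share the dark parent libraries, called 610 genes higher in both (358 for independent lists) and 967 lower in both (519), with r = 0.43. With no effect, 20 simulations gave a mean r of 0.51. The covariance was 1.08, above the 0.0699 simulated and the 0.194 from the spread of the dark parent replicates. The simulation gave each gene the same spread in all groups. Neither value holds a shift common to all dark parent samples, which would enter both comparisons. The excess therefore cannot be told apart from such a shift, and part of the overlap may come from the shared libraries.

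The 24 identifiers at the end of series D were near 0 in the deletion strain, some of them in the parent too. Low depth is argued against by 47 counts in light, where the parent level predicts 5339, and a general loss at series ends by the other 13 ends, where at most 18.2% of combinations of gene and light condition were below 5% of the parent. Whether the stretch is missing from the deletion strain stays open. Of its 21 combinations with at least 60 parent counts, 0 kept 5% or more, replicate 1 of the dark deletion strain left out, but the stretch was picked for being near 0, so this tests nothing. Counts do not separate a missing stretch from a silenced one, and the remaining counts of TrD1440W were not traced.

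Replicate 1 of the dark deletion strain held 9.01% of the parent level of 9 markers (6.63% with all 12). Of the 289 counts of the 9 markers, 189 were of TrC0725W. Reads of 1 deposited parent library mixed in are argued against: for each of the 6, at least 5 genes above 100 CPM stood at 3.73% or less of the parent library, under the share needed with either marker set. Parent-type cells in that culture could account for it, but the values leave this open. Among 1604 genes above 100 CPM in all dark parent libraries, the fifth-lowest stood at 7.72% of the lowest parent level, under the lower limit of the share from 9 markers (8.0%) and above that from 12 (6.15%). The choice of markers therefore decides the outcome of this test, and the limits cover counting error only, not differences between single markers. Outside the markers, 15 genes were under 2% of the dark parent level in the other 2 dark deletion libraries. In replicate 1 they stood at a median of 7.61% (3.29 to 13.6). They were picked for being low in the other 2 libraries, so this does not decide the question.

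The 105 genes graded among the dark parent libraries took 6.12% of counts in replicate 2, 1.21% in replicate 1 and 0.141% in replicate 3. RNA of another group mixed in is argued against, since 7 of the 105 reached the replicate 2 level in any other group. A gene programme that varies between samples is a candidate explanation. Within each other group, the spread of 102 of these genes, those abundant enough to be matched, lay at or above percentile 99.55 of 10000 random lists. The lists were matched on mean expression over all libraries. That mean includes the dark parent, where these genes were picked for being high. The match may therefore fail within the other groups, and the percentiles do not decide the question. In light in the deletion strain the spread of these genes was 0.14 on the log2 scale, below the highest of the lists (0.195), and what drives it was not tested.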
